A study of Drosophila melanogaster with 75 samples.

How the data were processed

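Labelled RNA from 15 pools of male heads (20 males a pool, 3 arms of 5 pools) was hybridised to 15 Affymetrix Drosophila arrays, per the labels. The authors processed the 15 arrays in 5 ways and deposited 75 columns of values, 1 for each array and processing: dChip PM (perfect-match probes), dChip PM-MM (perfect match minus mismatch), MAS5, GC-RMA in R and GC-RMA in GeneSpring, per the labels. The submitters' processing notes name GCOS 1.2 and GCRMA. The deposited values are intensity on a linear scale, judged from their range, and the normalization behind the dChip and MAS5 values and the software versions of dChip, R and GeneSpring are not given in the sources used here. GC-RMA subtracts a background modelled from probe sequence, normalizes across arrays and combines probes, which narrows the spread of dim probe sets. PM-MM subtraction leaves dim probe sets near 0 and noisy.

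Log2 was taken of every value here. In the PM-MM columns 746 values below 1, of which 40 were 0, were set to 1 first. The R GC-RMA columns were the main values, and the other 4 processings were alternatives. Of 18952 probe sets 183 AFFX controls were left out, and the 8926 of the remaining 18769 whose mean log2 value over the 15 arrays was at least 4 were tested (the lowest log2 value in the R GC-RMA columns was 1.64). A one-way limma model (lmFit and eBayes) over all 15 arrays gave the 3 contrasts courtship against control, male against control and courtship against male, with 12 residual degrees of freedom and a prior of 2.6. p-values are two-sided and were adjusted by Benjamini-Hochberg within each contrast, with a threshold of 0.05. limma 3.58.1 ran in R 4.3.3, and figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

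Gene names came from the platform annotation given for these probe sets, which is old. It gave 13647 probe sets 1 symbol, 402 several and 4720 none. A current gene table, used for names only, changed 0 symbols. Among tested probe sets 7886 had 1 symbol, 228 several and 812 none, for 7313 genes, and only probe sets with 1 symbol were named. No genome coordinates were used.

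Of 31 gene lists fixed in advance, 27 had at least 5 measured members and were tested with limma's camera at a preset correlation of 0.01, each gene represented by its probe set with the highest mean, with Benjamini-Hochberg over the 27 lists. camera compares a list with all other genes. It was repeated with the correlation estimated for each list, with fry, and as an exact permutation test of the list means per array (5 against 5 arrays). Some genes stand in more than 1 list, and heads hold all the tissues that the muscle, fat body, haemocyte and glia lists mark. Single members were also adjusted over the list alone.

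The arms, the model, the filter, the gene lists, most other settings tried and the rule for named genes were fixed before the data were examined. Named genes are, per contrast, the 12 higher and 12 lower with the smallest p among probe sets past the threshold, or, where fewer than 10 passed, the 8 higher and 8 lower by unadjusted p with 1 sign in R GC-RMA, MAS5 and dChip PM. To these were added up to 4 members of each list past 0.05 over the list alone, or up to 2 leading members of a described list with none. This gave 97 genes, and 25 lists were described because a test called them or a member, or because they were set to be described.

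The settings tried besides the main one were the other 4 processings, other filters, array scalings, blocks for the replicate number and for the first letter of the sample code, only the arms compared, other variance settings, array weights, a threshold of 0.10, and each array left out in turn. Models without male arrays 1 and 5, without these and control array 1, and with the mean log2 3'-to-5' ratio of 5 control pairs as a covariate were added after the arrays had been inspected, as was the exact permutation test of list means. Labels give the arms the same replicate numbers 1 to 5 and no statement that a number marks a shared batch.

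The model was tested on simulated data built from the spread of 8926 probe sets, 100 of which were changed by each fold. At 1.5-fold 61 of 100 were recovered in courtship against control, 71 in male against control and 67 in courtship against male, and at 2-fold 91, 87 and 90, with 11, 8 and 8 false calls. In simulated data for male against control, 20 draws without a changed list gave 1 call over 27 lists each, and when 1 list was raised by 0.3 it was called along with 1 other list. The simulation draws genes independently, which real genes are not. It also gives all arrays the same spread and plants both folds in the same data, which eases the adjusted threshold. Its recovery therefore does not carry over to a contrast with few or no changed genes.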

Results

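Gene expression was measured in the heads of 5-day-old males of an isogenized Canton-S line, a laboratory wild type of the fruit fly Drosophila melanogaster, on Affymetrix Drosophila arrays. The 15 arrays fell into 3 arms of 5, and each array carried RNA from its own pool of 20 males, so that p-values measure the spread between pools. Males of the courtship arm spent 20 min with a cauterized virgin female, and males of the control arm were handled for 20 min without a female. The 3rd arm is titled male. Its treatment label repeats that of the courtship arm. The title, the source name and the sample code set it apart (AMMH, for example, against AMFMH for courtship and AMH for control). None of these states what the males met, so that is not settled by the labels. A statement that the collected males courted for 70% of the time stands in the labels of all 3 arms, the control arm included. Values are log2 of the GC-RMA intensities that the authors computed in R, and 8926 of 18769 probe sets (47.6%) were bright enough to be tested.

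RNA from 3 pools stood apart. The mean log2 ratio of 3' over 5' signal of 5 control transcript pairs, which rises as RNA is degraded, was 3.25 on male array 1, 2.92 on control array 1 and 2.67 on male array 5, against 2.11 to 2.30 on the other 12 arrays. The 18S ribosomal RNA 3' probe set read 7.84 on male array 1 and 10.6 to 11.9 on the others. On the first principal component, which held 45.9% of the variance, male array 1 lay at -46.2 and male array 5 at -38.3, with the other arrays between -7.29 and 24.4. Correlations between arrays ran from 0.939 to 0.996, and the number of arrays limits the precision of every value here.

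**Figure D1:**
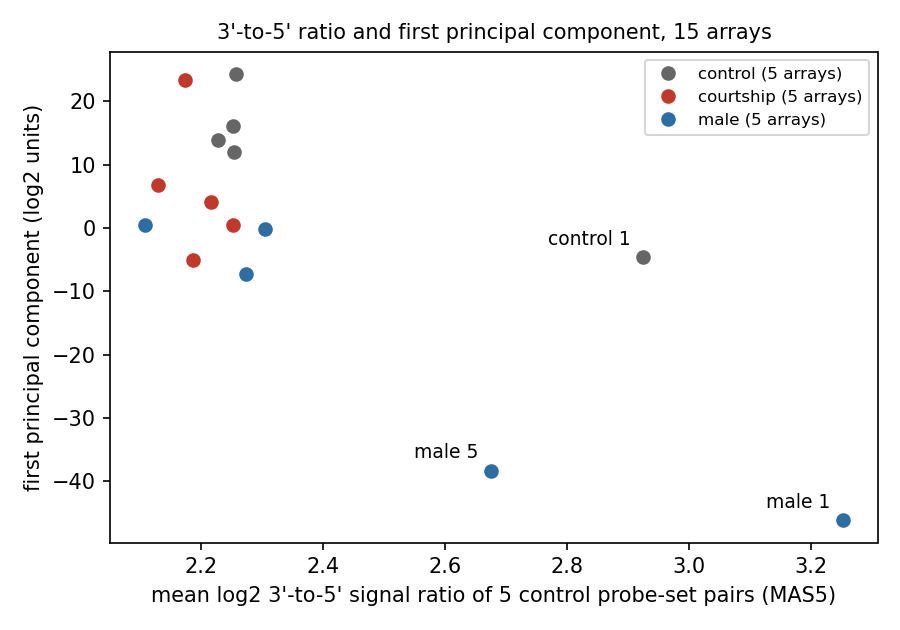
Each point is 1 of the 15 arrays, with the mean log2 3'-to-5' signal ratio of 5 control probe-set pairs on the horizontal axis and the first principal component of the log2 GC-RMA values on the vertical axis, coloured by arm. Male array 1 (3.25) and male array 5 (2.67) lie lowest on the component. Control array 1, with a ratio of 2.92, lies below the other control arrays but within the range of the remaining arrays.

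The first comparison, courtship against control, asks which transcripts of the head differ after 20 min of courting. The 4 smallest p-values belonged to hry, E(spl)mbeta-HLH, sug and CG11529, all higher in courting males. hry, or hairy, a basic helix-loop-helix repressor, stood at 12.28 ± 0.20 (SD, n = 5, log2) in courting males and 11.60 ± 0.09 in controls, a 1.60-fold difference. E(spl)mbeta-HLH, a target of Notch signalling, stood at 7.69 ± 0.21 against 7.05 ± 0.18, 1.56-fold higher. cwo, the clock repressor clockwork orange, stood at 7.50 ± 0.31 against 6.82 ± 0.12 on the dimmer of its 2 probe sets, while the brighter differed by 0.05 ± 0.14 (SE). The sugar-responsive zinc-finger gene sug was 1.71-fold higher and CG11529 was 1.76-fold higher. Sh, the Shaker voltage-gated potassium channel, was 1.37-fold lower and the calcium- and calmodulin-dependent phosphodiesterase Pde1c was 1.26-fold lower.

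None of these differences passed the threshold over all genes. limma called 0 of 8926 probe sets at an adjusted p of 0.05, with a smallest adjusted p of 0.180 (hry, E(spl)mbeta-HLH, sug and CG11529). At an unadjusted p under 0.05 there were 255, where chance gives 446. The adjusted p was 0.614 for cwo and 0.389 for Sh. The authors' other processings gave 0 calls with MAS5 (287 unadjusted) and 0 with GeneSpring GC-RMA (297 unadjusted), but hry and E(spl)mbeta-HLH passed in dChip PM (adjusted p = 0.0111 and 0.00514) and in dChip PM-MM (0.0479 for each). limma's array weights gave 12 calls, 6 higher and 6 lower, and leaving out courtship array 2 gave 4.

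The remaining genes named for this comparison, by unadjusted rank, went both ways. CG10621 was 1.53-fold, CG9377 1.79-fold and olf186-M 1.34-fold higher. Lower were the RNA-binding protein gene Hrb98DE (1.31-fold), CG6845 (1.32-fold), the cytochrome P450 gene Cyp28d2 (1.31-fold), Gfat1 (1.55-fold), which starts hexosamine synthesis, the splicing factor gene mbl (1.44-fold) and pcx (1.34-fold). The only other probe set of Gfat1 and 2 of the 4 others of mbl pointed the opposite way.

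**Figure D2:**
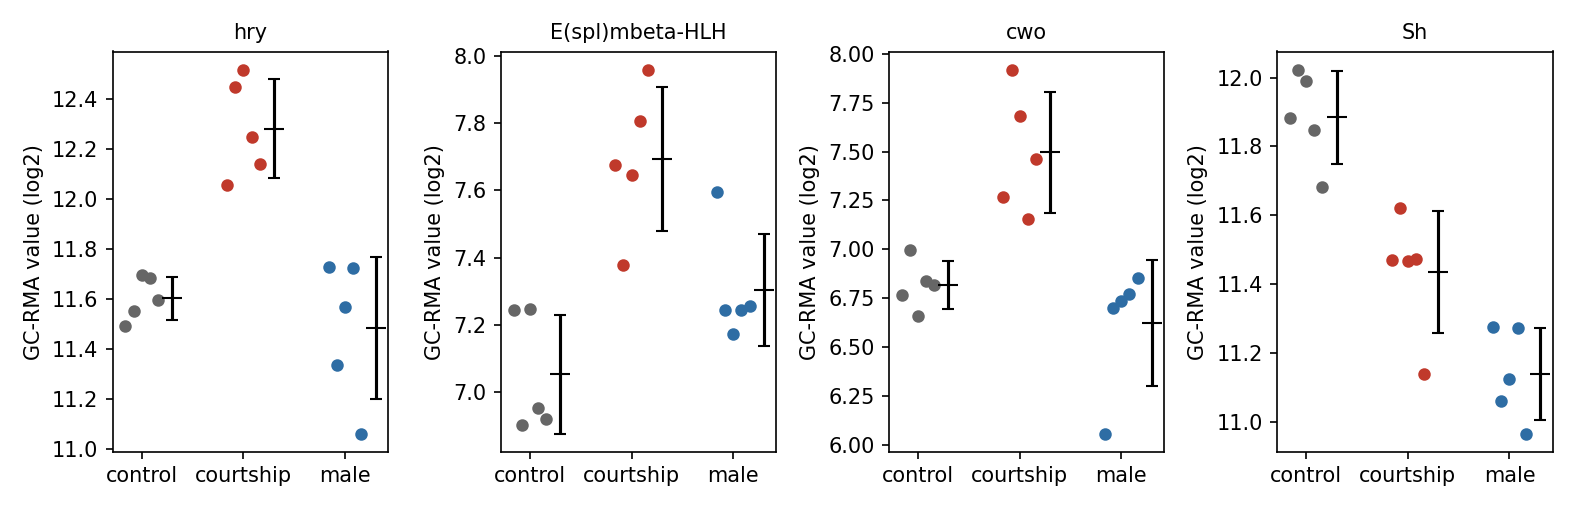
Log2 GC-RMA values (vertical axes) of hry, E(spl)mbeta-HLH, cwo (its dimmer probe set) and Sh in the control, courtship and male arms; each point is 1 array and the bar is the mean ± SD of 5 arrays. hry averages 12.28 in the courtship arm against 11.60 in controls and 11.48 in the male arm, while Sh steps down from 11.88 to 11.43 and 11.14.

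As groups, 3 gene lists lay lower and 5 higher in courting males than in controls, relative to all other genes. Synaptic and neuronal genes were lower in 25 of 26 measured members, with a median log2 difference of -0.12 (camera adjusted p = 3.24e-07), and Sh alone passed when adjusted over the list alone. Phototransduction genes were lower in 18 of 20 (median -0.06, adjusted p = 0.000989) and learning and memory genes in 14 of 15 (median -0.07, adjusted p = 0.0198). None of these 3 passed with an estimated correlation (adjusted p = 0.482 for each). Cytochrome P450 genes were higher in 46 of 55 (median 0.12, adjusted p = 0.00160), glutathione and UDP-glycosyl transferases in 37 of 44 (median 0.13, adjusted p = 0.00128) and odorant-binding proteins in 18 of 19 (median 0.11, adjusted p = 0.0138). Each of these 3 had adjusted p = 0.482 with an estimated correlation. Fat body genes, markers of another tissue, were higher too (10 of 14, median 0.07, adjusted p = 0.0567, past 0.05 in 3 of the 4 other processings), as were haemocyte genes (9 of 11, median 0.11, adjusted p = 0.139). The haemocyte rise sat in courtship arrays 4 and 5, whose list means were 0.49 and 0.46 above controls, against -0.01, -0.05 and -0.06 in arrays 1 to 3. Without array 4 or 5 its median was 0.03 or 0.07, and that of fat body genes was 0.05 without array 5 and 0.03 without control array 1. Oxidative phosphorylation genes were higher in 51 of 56 (median 0.04) and glycolysis and sugar storage genes in 15 of 18 (median 0.07), each with adjusted p = 0.0198 (0.684 and 0.482 with an estimated correlation). No member of these 8 lists passed over all genes.

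These list calls rest on the small correlation preset in camera. An exact permutation test of the list means per array, adjusted over lists, passed none of them (synaptic genes -0.21, exact p = 0.0873). The synaptic and phototransduction calls held without any 1 array, while the number of lists called fell to 5 without control array 1, 2 without control array 2, 2 without courtship array 4 and 2 without courtship array 5. Other single arrays whose removal ended a call were control 3 for odorant-binding proteins, control 4 and courtship 3 for oxidative phosphorylation and control 5 for learning and memory genes. Over all arrays left out singly, the highest camera adjusted p was 0.357 for P450 genes and 0.133 for transferases. It was 0.121 for odorant-binding proteins, 0.194 for oxidative phosphorylation, 0.145 for glycolysis and 0.121 for learning and memory genes. In the authors' 4 other processings the learning and memory call was met in 1 and the glycolysis call in 2, and the other 6 in 3 or 4. Sizes rested on single arrays too. Without courtship array 5 the median was 0.05 for P450 genes, 0.05 for transferases, -0.06 for synaptic and -0.03 for learning and memory genes. Without courtship array 4 it was 0.08 for transferases and -0.04 for learning and memory genes, without control array 4 -0.08 for synaptic genes, and without courtship array 3 0.02 for oxidative phosphorylation genes. Without courtship array 2 medians were larger, at 0.20 for P450 genes, 0.20 for transferases, 0.18 for odorant-binding, -0.11 for phototransduction, -0.14 for learning and memory and 0.06 for oxidative phosphorylation genes, the last also without control array 1. With the 3'-to-5' ratio as a covariate 5 lists passed, with medians of -0.23 for synaptic, -0.15 for learning and memory and 0.07 for oxidative phosphorylation genes. The P450 (0.0541), odorant-binding (0.0681) and glycolysis (0.229) lists did not, although their medians of 0.12, 0.10 and 0.06 were close to those without it.

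No list outside these 8 passed in camera at the values, filter and model used for those calls. Activity-regulated genes, which neurons switch on after firing, were lower in 10 of 14 (median -0.05, adjusted p = 0.167), sex-determination genes in 7 of 9 (median -0.04, adjusted p = 0.0921) and genes of courtship and aggression in 10 of 14 (median -0.11, adjusted p = 0.0921, past 0.05 in 1 other processing). Cuticle genes had an adjusted p of 0.0711 and passed in 3 other processings. Ecdysone and juvenile hormone genes (0.310) passed only without control array 1 and male arrays 1 and 5 (0.0494) among the models run for each list. Of 19 measured insulin and fasting genes, sug (log2 difference 0.77) and the activin ligand gene daw (0.31) were higher when adjusted over the list alone. fit, 1 of 2 measured genes of the list of female material, was higher by 0.49 ± 0.17 (SE) when adjusted over that list alone. It passed neither over the courtship and aggression list, which also holds it, nor over all genes. Muscle genes split 9 to 9 (median 0.00, adjusted p = 0.630) and glial genes 9 to 7 (median 0.02, adjusted p = 0.630).

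Male against control gave its smallest adjusted p (0.0130) for Sh, which fell 1.68-fold in male-arm heads, from 11.88 ± 0.13 in controls to 11.14 ± 0.13 (SD, n = 5, log2). The proton-channel gene OtopLa fell 1.84-fold, Pde1c 1.37-fold, the POU-domain factor gene pdm3 2.14-fold and the splicing factor gene ps, or pasilla, 2.12-fold. Nepl5, a neprilysin-like peptidase gene, rose 1.54-fold from 8.20 ± 0.06 to 8.83 ± 0.18, and Srr, the serine racemase gene, rose 1.42-fold. CG9377 rose 2.25-fold and CG31664 2.02-fold.

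In all, 327 of 8926 probe sets passed in limma, 194 higher and 133 lower, against 3046 at an unadjusted p under 0.05 where chance gives 446. The calls held 179 higher and 100 lower named genes, with 36 probe sets without a single gene symbol. The median fold of the calls was 1.41 among the higher and 1.57 among the lower, and the largest folds were 2.80 and 6.15. Other named genes that rose were CG5335, CG31915, CG10165, CG7227, CG7560, CG5885, CG10184 and CG10621, from 1.28-fold (CG31915) to 1.87-fold (CG7227). Others that fell were CG17786 (2.02-fold), CG45263 (1.75-fold), Gfat1 (1.96-fold), mbl (1.75-fold), pcx (1.60-fold), the deubiquitinase gene faf (1.54-fold) and the histone methyltransferase gene gpp (1.55-fold). The other probe set of Gfat1, 1 of 2 others of faf and 1 of 4 others of mbl pointed the opposite way.

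The balance and the number of these calls moved with the processing and with single pools. GeneSpring GC-RMA gave 362 higher and 251 lower, dChip PM 156 and 244, dChip PM-MM 14 and 50, and MAS5 63 and 103, and 225 probe sets (109 higher, 116 lower) passed with 1 sign in at least 3 of the 5 processings. Leaving out control arrays 1 to 5 gave 586, 0, 16, 7 and 71 calls, courtship arrays 1 to 5 gave 37, 1027, 34, 41 and 716, and male arrays 1 to 5 gave 253, 26, 531, 514 and 21. Without male arrays 1 and 5 no probe set passed (1962 at unadjusted p under 0.05), nor without those and control array 1 (2293 unadjusted). All 327 passed among 708 with the 3'-to-5' ratio as a covariate. With the first letter of the sample code as a block, whose meaning the labels do not give, 980 passed, 239 of the 327 among them.

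**Figure D3:**
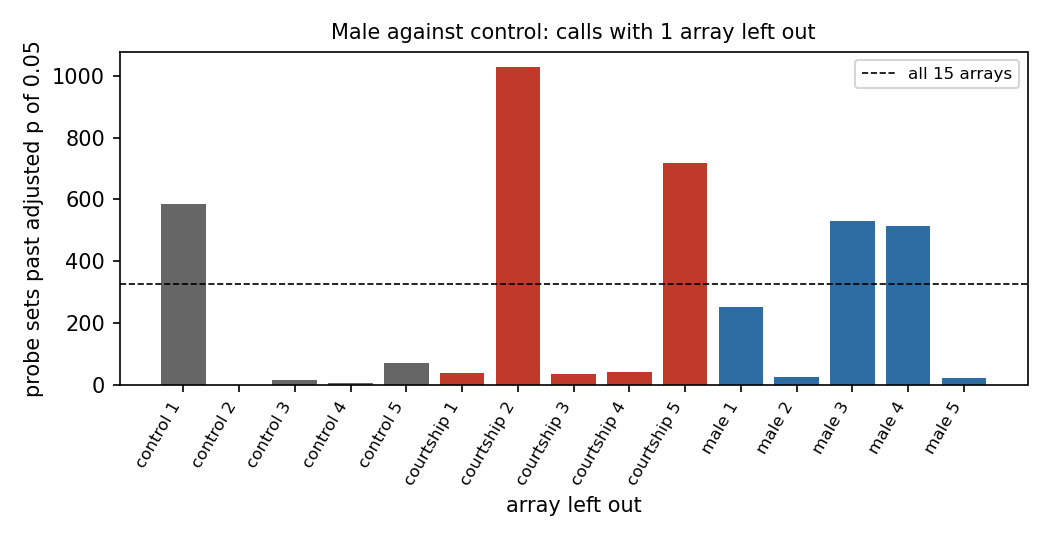
Bars give the number of probe sets past an adjusted p of 0.05 in male against control (vertical axis) when the array named on the horizontal axis is left out of the limma model; the dashed line marks the count with all 15 arrays. The count runs from 0 without control array 2 to 1027 without courtship array 2, against 327 with all arrays.

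Of 26 synaptic and neuronal genes 25 were lower in the male arm (median -0.43, or -0.28 without male arrays 1 and 5; camera adjusted p = 5.88e-09, but adjusted p = 0.367 with an estimated correlation), 3 fell over all genes and 17 fell when adjusted over the list alone. Those 3 were Sh, Shab, a second potassium channel (1.62-fold), and Rim, a scaffold of the presynaptic active zone (1.72-fold). Of 20 phototransduction genes 17 were lower (median -0.14, adjusted p = 9.91e-05, 0.367 with an estimated correlation), with the diacylglycerol kinase gene rdgA (1.52-fold) and the light-activated channel gene trp (1.27-fold) falling over all genes. Over the list alone 7 phototransduction genes fell and 1 rose. Clock genes (10 of 15 lower, median -0.14, adjusted p = 0.0315, 0.367 with an estimated correlation) included dco, the Doubletime kinase (1.33-fold), and nocte (1.56-fold), which fell over all genes. Learning and memory genes were lower in 11 of 15 (median -0.27, or -0.16 without male arrays 1 and 5; adjusted p = 0.00997), and the adenylyl cyclase gene rut, at -1.30 ± 0.35 (SE), or -0.85 without those arrays, passed over the list alone. Monoamine genes were lower in 15 of 20 (median -0.18, adjusted p = 0.0315), with the serotonin receptor gene 5-HT7 at -1.03 ± 0.28. For each of these 2 lists adjusted p = 0.367 with an estimated correlation. Leaving out 1 array moved 3 of these medians: learning and memory genes to -0.14 without male array 1, monoamine genes to -0.11 without control array 2, and clock genes to -0.07 without control array 1, -0.08 without male array 3 and -0.07 without male array 5. Neuropeptide genes did not pass and split 15 higher to 13 lower (adjusted p = 0.158).

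Activity-regulated genes (12 of 14 lower, median -0.11) and heat shock genes (6 of 6, median -0.25) each had an adjusted p of 0.0327 (0.367 with an estimated correlation), and the co-chaperone gene DnaJ-1 fell 1.37-fold over all genes. Most of the heat shock difference came from control array 5, without which the median was -0.08 and the list mean per array differed by -0.10 rather than -0.30. CG8910 led the activity-regulated genes at -0.38 with no member past its test. Muscle genes were lower in 16 of 18 (median -0.12, or -0.07 without male arrays 1 and 5; adjusted p = 0.00752, 0.367 with an estimated correlation), with the titin-like gene sls at -0.52 and Zasp66 at -0.29 (-0.16 without those arrays) and no member past its test. Glial genes did not pass as a list (10 of 16 higher, median 0.06, with camera's direction downward, adjusted p = 0.951), although the engulfment receptor gene drpr fell 1.33-fold over all genes.

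Cytochrome P450 genes were higher in the male arm in 50 of 55 (median 0.31, adjusted p = 3.82e-06), 2 rose over all genes (Cyp12a4, 1.49-fold, and Cyp9c1, 1.38-fold) and 12 rose when adjusted over the list alone. Glutathione and UDP-glycosyl transferases were higher in 41 of 44 (median 0.26, adjusted p = 9.99e-06), with 3 past the test over all genes, Ugt37B1 (2.48-fold), GstE11 (1.55-fold) and GstZ1 (1.48-fold), and 17 higher and 1 lower over the list alone. With an estimated correlation each of these 2 lists had adjusted p = 0.367. Fat body genes, markers of another tissue, were higher as well, in 11 of 14 (adjusted p = 0.0943), and so were haemocyte genes in 8 of 11 (adjusted p = 0.233). Their list means per array were higher by 0.19 (exact p = 0.00794, 0.0238 adjusted over lists) and 0.25 (exact p = 0.0159, 0.0390 adjusted over lists). Odorant-binding proteins were higher in 19 of 19 (median 0.21, adjusted p = 0.00997, 0.473 with an estimated correlation), led by Obp28a at 1.46 ± 0.42 (SE) with no member past its test. Oxidative phosphorylation genes were higher in 48 of 56 (median 0.10, or 0.05 without male arrays 1 and 5; adjusted p = 0.00283, 0.532 with an estimated correlation), led by the complex I subunit gene ND-B18 at 0.34, and cuticle genes in 15 of 17 (median 0.18, or 0.12 without those arrays and 0.30 without male array 4; adjusted p = 0.0492, 0.449 with an estimated correlation), led by Cpr67B at 0.36, again with no member past its test.

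**Figure D4:**
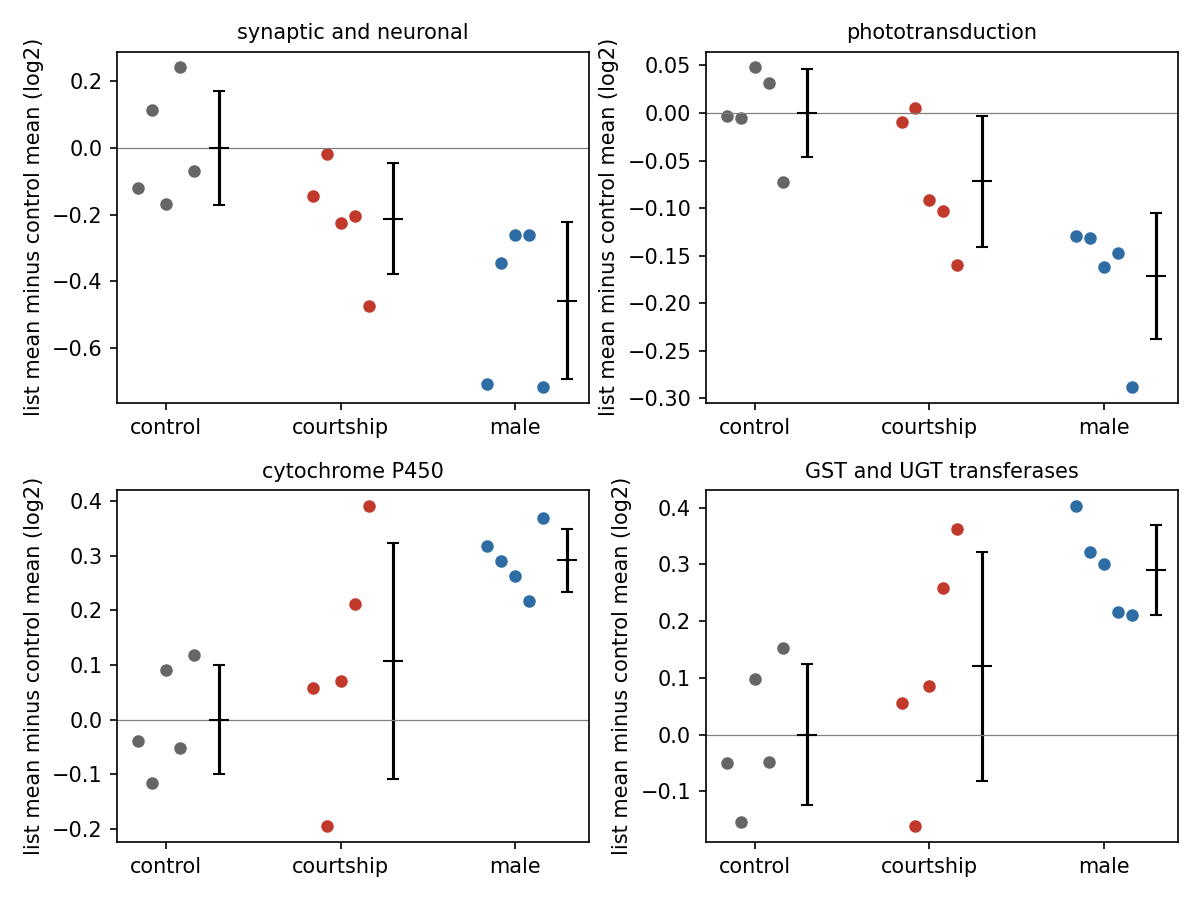
Mean log2 GC-RMA value of the measured members of 4 gene lists, minus the mean of the control arrays (vertical axes), for each array of the 3 arms; bars are the mean ± SD of 5 arrays. Synaptic and neuronal genes lie 0.46 below controls on average in the male arm and cytochrome P450 genes 0.29 above, with the courtship arm in between in each panel.

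Other tests bore on these 13 lists. fry, which asks whether a list moves one way without comparing it with other genes, passed 6 (synaptic, phototransduction, learning and memory, clock, P450 and transferase genes), and the exact permutation test of list means, adjusted over lists, passed 9 of the 13, the synaptic list among them at -0.46 (exact p = 0.00794, the smallest that 5 against 5 arrays can give). It did not pass muscle (0.0630), odorant-binding (0.0612), oxidative phosphorylation (0.0630) and cuticle (0.0790) genes. Calls were lost for activity-regulated genes without control array 2, male array 2 or male array 3 (adjusted p up to 0.0650), for heat shock genes without control array 5 or male array 1 (up to 0.209), for monoamine genes without control array 2 (0.0650) and for cuticle genes without any of 7 arrays (control 3 and 5, courtship 2 and 5, male 2, 3 and 5; up to 0.0954). Without male arrays 1 and 5, which had high 3'-to-5' ratios, the synaptic, P450 and transferase lists had adjusted p of 1.19e-07, 6.76e-07 and 3.50e-07. Muscle (0.0726) and cuticle (0.0788) genes then no longer passed. With the 3'-to-5' ratio as a covariate heat shock and cuticle genes, each at 0.0573, no longer passed, with medians of -0.21 and 0.20. Of the authors' 4 other processings 1 gave the cuticle call, and 3 or 4 gave each of the others.

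Other lists did not pass in camera at the values, filter and model used for those calls, though they held members that passed. Of the authors' 4 other processings, 3 called antimicrobial peptides, 2 fat body genes and 1 glycolysis genes. Of 15 antimicrobial peptide genes 12 were higher (median 0.24, adjusted p = 0.0657), Drsl5 rose 1.55-fold over all genes, and BomS4 (0.47) and BomS6 (0.27) also passed over the list alone. The adjusted p of this list was 0.0101 without male arrays 1 and 5 and 0.0489 with the 3'-to-5' ratio as a covariate, but up to 0.426 without 1 array. Its mean per array was 0.14 above controls (exact p = 0.690) and turned to -0.04 without male array 4, -0.05 without control array 3 and -0.01 without control array 4. Of 21 immune recognition genes 13 were higher (median 0.15, adjusted p = 0.179), with GNBP2 (1.41-fold) and the protease gene psh, or persephone (1.44-fold), rising over all genes and GNBP3 (0.52) passing over the list alone. Here the adjusted p was 0.0283 without male arrays 1 and 5 but up to 0.642 without 1 array. The list mean, 0.16 above controls (exact p = 0.317), was 0.08 without male array 4, 0.07 without control array 3 and 0.10 without control array 4. Insulin and fasting genes (11 of 19 higher, adjusted p = 0.667) held tobi, an insulin-responsive glucosidase gene that rose 1.82-fold, and the kinase gene Lk6, which fell by 0.27 on the log2 scale, with fbp (0.55) and Pepck2 (0.68), both of gluconeogenesis, among 5 higher over the list alone. Glycolysis genes (14 of 18 higher, adjusted p = 0.239) held the hexokinase gene Hex-C, up 1.60-fold, with UGP (0.38) passing over the list alone. Fat body genes (adjusted p = 0.0943, 0.0303 without male arrays 1 and 5, up to 0.232 without 1 array) held Lsp2 (0.76), the clotting gene fon (0.34) and regucalcin (0.51), which passed over the list alone. Of 19 ecdysone and juvenile hormone genes 11 were lower (adjusted p = 0.127, 0.0216 without control array 1 and male arrays 1 and 5), and the juvenile hormone receptor genes Met (-1.42 ± 0.41, SE, or -0.59 without male arrays 1 and 5) and gce (-1.02 ± 0.29) passed over the list alone.

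The sex-determination factor gene fru, needed for male courtship, fell 1.46-fold in the male arm, from 10.12 ± 0.12 to 9.58 ± 0.23 (SD, n = 5). It did not pass without male arrays 1 and 5, and neither did any other probe set. It was the only member of the sex-determination list (7 of 9 lower, adjusted p = 0.180) and of the courtship and aggression list (11 of 14 lower, adjusted p = 0.0561) to pass over all genes. The second list passed without male arrays 1 and 5 (0.0283), without those and control array 1 (0.0354) and with the 3'-to-5' ratio as a covariate (0.0418), but in none of the other processings. her was higher by 0.33 (0.21 without male arrays 1 and 5) and passed over the sex-determination list alone, but its difference was -0.014, -0.065 and -0.16 in dChip PM, dChip PM-MM and MAS5. Few genes of other tissues were measured. fit (0.46), Acp95EF of the male reproductive tract (0.23, the only measured member) and the lysosomal mannosidase gene LManI of the gut list (0.52, of 4 measured) were higher over their lists alone, and none of these passed over all genes. For fit that list was female material, and it did not pass over the courtship and aggression list, which also holds it. With 1 measured member, the adjustment left the p-value of Acp95EF unchanged.

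The comparison of courtship with male is also the test of how far their differences from control diverge. hry was 1.74-fold higher in courting males (12.28 ± 0.20) than in the male arm (11.48 ± 0.28, SD, n = 5, log2), and cwo stood at 7.50 ± 0.31 against 6.62 ± 0.32 on its dimmer probe set. comm2, of the commissureless family, was lower in courting males (log2 difference -0.59 ± 0.10, SE). Snp, an exonuclease gene, was 1.60-fold higher and the ubiquitin ligase gene HUWE1 1.55-fold higher, while the serpin gene Spn43Ad was 1.57-fold lower and Srr 1.32-fold lower. CG12290, faf (0.48, or 0.30 without male arrays 1 and 5), CG17786 and CG45263 were also higher in courting males, by 0.30 to 0.67 on the log2 scale, and CG11679, CG5704, CG9667, CG5335 and CG31915 lower, by log2 differences from -0.24 to -0.47.

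No probe set passed in limma over all 8926, with a smallest adjusted p of 0.0938 (hry and comm2) and 1354 at an unadjusted p under 0.05. hry passed in dChip PM, dChip PM-MM and GeneSpring GC-RMA (adjusted p = 0.0397 in the last, where comm2 also passed), the only probe set to pass in 3 of 5 processings, and MAS5 gave 0 calls. Other settings of the R GC-RMA values gave calls too: 2 after a repeated quantile normalization, 2 without male array 1, 1 without male arrays 1 and 5, 3 with array weights and 169 with the code letter as a block (100 higher, 69 lower), although the 2 arms do not share most letters. The hry call in 3 processings was fragile. No probe set passed in 3 with the 3'-to-5' ratio as a covariate, or without any single array other than male array 1.

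Relative to other genes, 5 lists were higher and 5 lower in courting males than in the male arm. Synaptic genes were higher in 24 of 26 (median 0.26, or 0.14 without male arrays 1 and 5; camera adjusted p = 6.73e-06), phototransduction genes in 17 of 20 (median 0.07, adjusted p = 0.00402) and muscle genes in 15 of 18 (median 0.14, adjusted p = 0.00105), each with adjusted p = 0.468 with an estimated correlation. Clock genes were higher in 9 of 15 (median 0.04, or 0.03 to 0.10 leaving out single arrays; adjusted p = 0.0293, 0.468 with an estimated correlation), with the brighter cwo probe set (0.45), dco (0.33) and Clk (0.84 ± 0.26, SE, or 0.52 without male array 1) past the test over the list alone. Heat shock genes were higher in 6 of 6 (median 0.13, adjusted p = 0.0347, 0.468 with an estimated correlation), and DnaJ-1 (0.41) passed over the list alone. P450 genes were lower in 52 of 55 (median -0.18, adjusted p = 6.13e-05), transferases in 40 of 44 (median -0.18, adjusted p = 0.000288), antimicrobial peptides in 14 of 15 (median -0.21, adjusted p = 0.0164), immune recognition genes in 17 of 21 (median -0.16, adjusted p = 0.0167) and oxidative phosphorylation genes in 45 of 56 (median -0.07, adjusted p = 0.0169). With an estimated correlation the adjusted p was 0.468 for P450, antimicrobial and immune genes, 0.475 for transferases and 0.721 for oxidative phosphorylation genes. Fat body genes were lower in 10 of 14 (adjusted p = 0.394) and haemocyte genes in 7 of 11 (adjusted p = 0.764).

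None of these 10 lists passed with fry or with the exact permutation test adjusted over lists. Calls were lost without courtship array 1 or 3 for heat shock, antimicrobial and immune genes. They were also lost without male array 1 or 3 for the first and male array 4 for the others. Over these arrays the adjusted p reached 0.111, 0.169 and 0.184. The oxidative phosphorylation call was lost without courtship array 1 or 2 or male array 5 (up to 0.146), so that 6 lists passed without courtship array 1. Without courtship array 2 the median was -0.08 for P450 genes and -0.10 for transferases, and without courtship array 5 -0.28 for P450 genes. Without male array 1 it was 0.13 for phototransduction genes. Without male array 4 it was -0.10 for immune genes, and the mean difference of antimicrobial peptides was -0.20 rather than -0.37. Without male arrays 1 and 5 the adjusted p was 0.0544 for clock genes (median still 0.04) and 0.578 for oxidative phosphorylation genes (median -0.01), and the median was -0.31 for antimicrobial and -0.26 for immune genes. With the 3'-to-5' ratio as a covariate the adjusted p was 0.0575 for clock genes, 0.142 for heat shock genes and 0.232 for oxidative phosphorylation genes, with medians of 0.10, 0.10 and -0.02. Outside these lists, fru was higher by 0.37 and her lower (-0.32, or -0.20 without male arrays 1 and 5, but 0.055, 0.074 and 0.020 in dChip PM, dChip PM-MM and MAS5), both over the sex-determination list alone, and so were Lk6 (0.20) and Pepck1 (-0.28) over the insulin and fasting list. cbt led the activity-regulated genes at 0.26 (0.17 without male array 1) with none past its test (12 of 14 higher, adjusted p = 0.0691). That list passed without male arrays 1 and 5 (0.0328), without those and control array 1 (0.0436) and in 2 of the 4 other processings. Odorant-binding proteins (0.0890) passed with the covariate (0.0320) and in 1 other processing, monoamine genes (0.0691) in 3 and learning and memory genes (0.0652) in 1. Of the 10 lists called, heat shock genes passed in 2 other processings and the rest in 3 or 4.

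Across the 8926 probe sets, which are not independent replicates, the log2 differences of both arms from control correlated at 0.648, where unchanged groups set against the same controls gave a mean of 0.477 and reached the observed value in 30 of 100 draws. Their covariance was 0.0341, where unchanged groups gave 0.0173 on average and 10 of 100 draws were as large. With the controls split between the comparisons, over 10 divisions, the median correlation was 0.374 (from -0.124 to 0.630) and the median covariance 0.0251.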

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

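The explanations weighed in this part were set up after the result was seen; the counts over other splits of the arrays were planned.

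Within an arm of 5 arrays, a value stood out when the gap from the highest or lowest array to its neighbour took over 0.71 of the arm's range. Of 399 values tested 29 did so, where chance gives about 20, and 11 of them came from male array 5 and 10 from male array 1, against 3 from control array 5, 2 each from control array 1 and courtship array 2, and 1 from control array 3.

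In the male arm, array 5 stood apart for HUWE1 (0.765 of the range), ps (0.88), gpp (0.725), drpr (0.719), rut (0.745), 5-HT7 (0.855), Calx (0.819) and the phototransduction list (0.794), all lowest there, and for Cyp12a4 (0.822), fon (0.736) and psh (0.876), all highest there. Male array 1 stood lowest for cwo (dimmer probe set, 0.806), Clk (0.802), Shaw (0.907), the 18S 3' signal (0.777) and the means of the monoamine (0.73) and glycolysis (0.72) lists. It stood highest for E(spl)mbeta-HLH (0.8), CG9377 (0.72), the clock gene tim (0.818) and the mean of the chemoreceptor list (0.857).

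In the control arm, array 1 stood highest for the 3'-to-5' ratio (0.957) and for tim (0.821), a gene outside the naming rule that was examined only for a test of the time of day. Control array 5 was highest for Drsl5 (0.713) and the heat shock list (0.887) and lowest for the sex-determination list (0.714), and control array 3 was highest for Shab (0.784). In the courtship arm, array 2 stood highest for Lk6 (0.71) and Shab (0.823).

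The 327 calls between the male and control arms were weighed against 3 technical explanations. Bias of the RNA towards 3' ends on a few arrays is argued against only for the fall of synaptic genes. These were lower in male arrays 2, 3 and 4, whose ratios were not raised, than in controls (log2 difference -0.29, exact p = 0.0357, the smallest that 3 against 5 arrays can give). For the 327 calls it stays open. All of them passed among 708 with the 3'-to-5' ratio as a covariate, but the ratio did not track how far arrays stood apart. On the first principal component control array 1, with a ratio of 2.92, lay at -4.59 and male array 5, with 2.67, at -38.3. A lower share of nervous tissue is argued against only in the form where all other tissues gain alike. Fat body genes were higher (0.19) and muscle genes lower (-0.17), 0.365 apart (exact p = 0.00794). A shift that differs between the other tissues was not tested and stays open, and haemocyte genes were higher too (0.25). Glial genes, which also mark nervous tissue, were not lower (0.05, exact p = 0.492). The muscle median was -0.12, or -0.07 without male arrays 1 and 5. Whether male arrays 1 and 5 carry the calls stays open. Their removal left 0 calls, the lowest a count can be, and so did that of the 3 other pairs that include male array 5, while pairs of male array 1 with array 2, 3 or 4 left 3, 65 and 10 and pairs with neither left 61, 500 and 1723. At an unadjusted p under 0.05, however, 1962 probe sets remained without both, within the 1906 to 3449 of the other pairs. Without array 1 alone 253 passed the adjusted threshold, but without array 5 alone only a small part of that number did. The log2 differences without both correlated at 0.854 with those of all arrays, below the 0.928 to 0.978 of the other pairs. A difference in what the male arm met may also account for the calls, and stays open, because the labels do not say what it was.

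Chance was assessed by regrouping the arrays of each comparison into other sets of 5 and 5, over 100 splits with the real one included. For male against control it is unlikely but not excluded: only the real split reached 327 calls (1 of 100, highest other 140) or 225 probe sets in 3 processings (1 of 100, highest other 124), and 2 of 100 reached 13 lists (highest other 14). The splits cannot tell an effect of the arm from outlying arrays that happen to share it, as male arrays 1 and 5 do. For the lists of courtship against control chance was common, since 42 of 100 splits gave at least the 8 lists (highest other 14), and so it was for those of courtship against male, where 19 of 100 gave at least the 10 (highest other 16). A count of 0 is reached by every split whatever the values are, so for the 0 calls of courtship against control (100 of 100, highest other 4), its 0 in 3 processings (100 of 100, highest other 4) and the 0 calls of courtship against male (100 of 100, highest other 1) the splits say nothing. For courtship against male the 1 probe set in 3 processings, hry, was reached by the real split alone (1 of 100, highest other 0). That count was 0, however, with the 3'-to-5' ratio as a covariate and without any single array other than male array 1.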

How the results depend on the processing

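The models without male arrays 1 and 5, without those and control array 1, and with the 3'-to-5' ratio as a covariate, the exact permutation test of list means, and the leave-one-out values of list means and medians, of the counts over processings and of the correlation were chosen after the data had been seen; the rest was planned. Where a cause is not named below, the cause was not tested.

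The correlation of both differences from control (0.648) ran from 0.485 without courtship array 5 to 0.782 without control array 1. No named gene past its threshold changed sign under any setting run. Of the 44 named calls, all in male against control, GeneSpring GC-RMA, the replicate block and the covariate kept 44, the code letter 39, dChip PM 34, MAS5 23, dChip PM-MM 17, and the model without male arrays 1 and 5 kept 0. None of the 44 was kept in every model that left out 1 array. her, which did not pass over all genes, reversed: against control the male arm gave -0.014 in dChip PM, -0.065 in dChip PM-MM and -0.16 in MAS5, and courtship against male 0.055, 0.074 and 0.020.

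The 327 calls of male against control became 64 in dChip PM-MM, 166 in MAS5 and 613 in GeneSpring GC-RMA. Arrays centred on their medians gave 572 and a repeated quantile normalization 743. Keeping all probe sets gave 12, and a filter at a mean log2 of 6 gave 625. A trended robust prior gave 631, array weights 1873, only the 2 arms compared 495 (379 higher, 116 lower), a threshold of 0.10 gave 2083, the code letter 980 as a fixed and 1465 as a random block, and the covariate 708. Without male arrays 1 and 5, and without those and control array 1, 0 passed. Leaving out single arrays gave 0 (control 2) to 1027 (courtship 2), with 586, 16, 7 and 71 for control 1, 3, 4 and 5, 37, 34, 41 and 716 for courtship 1, 3, 4 and 5, and 253, 26, 531, 514 and 21 for male 1 to 5.

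The 225 probe sets in at least 3 processings became 36 in all 5, 440 in at least 2, 540 with the covariate and 0 in both models with fewer arrays. Leaving out single arrays gave 0 (control 2) to 755 (courtship 2), with 369, 13, 3 and 73 for control 1, 3, 4 and 5, 35, 33, 58 and 534 for courtship 1, 3, 4 and 5, and 194, 16, 458, 391 and 13 for male 1 to 5.

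Courtship against control (0 calls) gave 2 in dChip PM, 2 in dChip PM-MM and 12 with array weights, and 0 to 4 (without courtship array 2) leaving out single arrays. Over processings its count of 0 became 2 in at least 2 of 5, 2 without male arrays 1 and 5, 1 with the covariate, and 0 to 2 leaving out single arrays (2 without courtship array 2, 1 without male array 1). Courtship against male (0 calls) gave 1 in dChip PM, 1 in dChip PM-MM, 2 in GeneSpring GC-RMA, 2 after quantile normalization, 169 with the code letter, 3 with array weights, 1 without male arrays 1 and 5, 2 at a threshold of 0.10, and 0 to 2 (without male array 1) leaving out single arrays. Its count over processings, 1, became 0 in all 5, 2 without male arrays 1 and 5, 0 with the covariate, and 0 to 2 leaving out single arrays (2 without male array 1, 0 without any other).

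The lists called (8, 13 and 10) became 0, 0 and 0 with an estimated correlation, 0, 6 and 0 with fry, and 0, 11 and 0 with the exact permutation of list means (9 of the 13 in male against control, plus fat body and haemocyte genes). The covariate left 5 in courtship against control, and keeping all probe sets gave 17 in courtship against male. Leaving out single arrays gave 2 (control 2, courtship 4 or courtship 5; 5 without control 1) to 12, 11 to 16, and 6 (courtship 1) to 15.

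The labels do not say what the array number or the code letter stands for, and some arrays of the same number also share the letter. Of 15 pairs of arrays with the same number, 10 had deviations correlated over 0.1 (from -0.288 to 0.473, mean 0.163, against -0.0019 for all pairs across arms), and 6 of 15 arrays correlated best with their own number. With the number as a replicate block 1690 probe sets passed in male against control, 845 each way, the 327 among them, and no other count of calls made with that block moved by over 1.5 times.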

Other observations

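The tests were chosen after the ranking of genes and the arrays had been seen, that of the time of day also after its result; the criteria for the gene family and for control array 1 were written before their own values were seen.

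Some gene groups fixed in advance have been described only in part or not at all. Neuropeptide genes split 15 higher to 13 lower in male against control (camera adjusted p = 0.158, with a median of 0.01 and a mean of -0.11) and 13 to 15 in courtship against control (adjusted p = 0.670). In courtship against male their adjusted p was 0.0958, but 0.0450 without male arrays 1 and 5, 0.0436 without those and control array 1 and 0.0109 with the 3'-to-5' ratio as a covariate, upward. Over all arrays it was 0.638 with an estimated correlation and 0.452 with fry. Cytosolic ribosomal protein genes were higher in 25 of 29 in each of these comparisons, by medians of 0.04 and 0.02 (adjusted p = 0.157, past 0.05 in 1 of the 4 other processings, and 0.356). Odorant, gustatory and ionotropic receptors, with 8 measured of 172 on the array, were higher in 7 of 8 in the male arm (median 0.04, adjusted p = 0.667) and 6 of 8 in courting males (median 0.11, adjusted p = 0.248). Of 5 measured genes of pheromone and hydrocarbon synthesis 3 were lower in the male arm (adjusted p = 0.690) and 3 higher in courting males (adjusted p = 0.630). The only measured Turandot stress gene was higher by 0.73 in courting males and by 0.64 in the male arm.

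The median, the mean or the camera direction of a list differed in sign in 12 cases, none of them a list that passed. For antimicrobial peptides in courtship against control, for example, 9 of 15 members were higher (median 0.08) while the mean was -0.24 (adjusted p = 0.932).

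hry, E(spl)mbeta-HLH and cwo, higher in courting males by 0.67 on average, are repressors of the same basic helix-loop-helix-Orange family, although the brighter cwo probe set differed by 0.05. A common rise of that family is a hypothesis that stays open, because only 1 other member was bright enough to be tested, E(spl)m3-HLH, named here because the test needed it. Its difference was 0.51 (exact p = 0.0238), which met the criterion written beforehand, and a minimum of 3 members was set only after that value was seen. A shift in time of day is argued against only as the source of the rise on the dimmer cwo probe set, which differed by 0.68. tim, per, vri and Pdp1, which cycle with cwo, differed by -0.11 ± 0.08 (SE) on average (exact p = 0.246), each of them lower (from -0.05 to -0.14). Against the 0.05 of the brighter cwo probe set these values cannot decide, since their spread reaches it. The high 3'-to-5' ratio of control array 1 is argued against too, since the mean difference of hry, E(spl)mbeta-HLH and cwo (dimmer probe set) was 0.66 ± 0.06 with the ratio as a covariate. That SE does not allow for the choice of these genes by their difference in the same arrays. Handling or activity other than courting may differ between the arms as well, and was not tested.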
